A study of Mus musculus with 14 samples.

How the data were processed

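RNA from mouse haematopoietic stem cells (HSCs) was measured on 14 Affymetrix Mouse Gene ST arrays, 1 array per sample. Per the labels, the cells were CD150+CD48- LSK cells, that is lineage-negative, Sca-1-positive, Kit-positive marrow cells with the SLAM marker pattern of stem cells, and each sample was sorted in a pair of successive rounds. Total RNA was isolated with a miRNeasy kit and amplified with the NuGEN Pico method before biotin labelling, per the labels' protocols. Amplification from small amounts of RNA can compress or distort differences between transcripts, and the arrays were not checked for it here.

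The values used were the processed log2 expression values that the authors deposited, 1 value per probe set and array. They were made with RMA in the affy package, per the submitters' processing notes. RMA subtracts background, quantile normalises the arrays and summarises the probes of a probe set. The versions, the genome build and the grouping of probes into probe sets were not given in the sources used here. The sorted values of the columns were close to but not equal to each other. The largest deviation of a column from the mean quantiles was 0.17 log2 units, and the array medians lay between 5.01 and 5.12. Depth does not apply to arrays, and the number of arrays per group limits the precision.

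The table held 21225 probe sets. The annotation given paired 20239 of them with exactly 1 gene symbol, and all 20239 matched the reference gene table used for names, from the mouse assembly GRCm38.p6. No gene had a second probe set, so the planned fit on every probe set with 1 symbol was identical and is not listed again. The other 986 probe sets were unnamed here and were left out of the comparisons. They were tested apart from the named ones only to count calls. Some further genes of the lists, among them Cd38, Ly6a and Trp53, were not analysed here. No coordinates are given because the build behind the probe sets was not stated. The reference table was used only for names and for which genes neighbour Sh2b3.

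Samples were grouped by the genotype and age in their labels. The 4 groups were wild type at 2 months (n = 3), Lnk-null at 2 months (n = 3), wild type at 20 months (n = 4) and Lnk-null at 20 months (n = 4). The labels number the arrays as biological replicates and do not say how many mice gave each sample. The comparisons were age within each genotype (old minus young), genotype within each age (Lnk-null minus wild type), the age by genotype interaction (the age effect in Lnk-null minus that in wild type) and the mean age effect over both genotypes. All calculations were run in R 4.3.3 with limma 3.58.1. A mean per group was fitted to each gene over all 14 arrays with lmFit, and variances were moderated with eBayes with a trend on the mean level. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 20239 genes within each comparison, and genes were called at an adjusted p under 0.05. Standard errors (SE) are limma's coefficient errors with the moderated variance. Folds are 2 to the power of the log2 difference. Single values such as group differences on a score were tested with two-sided exact permutation tests.

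The tests, the 29 gene lists, the rule for named genes and all alternatives except those given as added later were fixed before the data were examined. The named genes were Sh2b3 and, in each comparison, the 12 largest rises and 12 largest falls among called genes whose arrays did not overlap between the groups (all called genes where fewer than 10 passed). To these were added the 4 members with the smallest p of each called list, and Selp, Vwf, Slamf1, Procr, Flt3, Jak2, Cish, Cdkn1a and Cdkn1c throughout. Predicted genes, RIKEN clones, olfactory and vomeronasal receptors, small RNAs and antigen receptor segments were counted and not named, with 1 exception given where it stands.

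The lists were HSC ageing higher and HSC ageing lower (genes recalled from earlier studies of HSC ageing), HSC identity, lymphoid priming and B lineage, myeloid, megakaryocyte and platelet, erythroid, mitosis, DNA replication, p53 targets and CDK inhibitors, JAK2 and STAT5 signalling, immediate-early, interferon response, NF-kappaB and inflammation, TGF-beta and BMP signalling, DNA repair, DNA methylation and Polycomb, redox and FoxO, heat shock and protein folding, oxidative phosphorylation, glycolysis and hypoxia, ribosomal protein, adhesion and niche, and sex-linked genes. Further lists held markers of T and NK cells, macrophages, endothelial and stromal cells, mast cells and basophils, and plasma and mature B cells. Lists with at least 5 measured genes were tested with limma's camera, which asks whether a list ranks higher or lower than the other genes. The preset inter-gene correlation of 0.01 was used, with adjustment over the 29 lists of a comparison. The same test with an inter-gene correlation estimated from the residuals of each list was the alternative, and its adjusted p is given as "with an estimated correlation". List members were also counted with limma p-values adjusted over the list alone. Camera was run the same way on genes within 10 Mb of Sh2b3. Lists overlap: 15 of the 42 measured HSC ageing higher genes, 18 of the 24 HSC ageing lower genes, 2 of the 19 macrophage markers, 2 of the 17 plasma and mature B cell markers and 1 of the 20 T and NK markers belong to another list as well.

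For the size of the age response, genes called for the mean age effect were used, since that choice does not favour either genotype. The age effect of each gene was signed by its mean direction and averaged over genes. An age score per array was the signed mean over these genes relative to the wild-type young mean. Genotype labels were permuted within each age over all 1400 arrangements. Outlying arrays within the groups of 4 were sought with Dixon's test for each named gene.

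The fits were tested on simulated data with the residual spread and the group sizes of these arrays, 20239 genes and 200 changed genes. Genes simulated at 2-fold were recovered at 98.5% for age in wild type, 94.0% for age in Lnk-null, 88.1% for genotype in old, 97.0% for genotype in young and 80.6% for the interaction. At 1.5-fold the recovered shares were 77.6%, 65.7%, 73.1%, 61.2% and 41.8% in the same order. At 4-fold they were 100%, 100%, 98.5%, 98.5% and 97.0%. False calls numbered 6, 12, 11, 14 and 12 in the same order, among 20039 unchanged genes. A list of 29 genes shifted by 0.3 log2 units was found in each of the 4 pairwise comparisons, and a simulated ratio of age responses of 0.6 was found as 0.611. Genes were simulated independently of each other, so these checks do not show how the list test or the ratio behaves when genes are correlated. Benjamini-Hochberg adjustment is also less strict where many genes change. The recovered shares thus hold for 200 changed genes and can overstate recovery where few genes change. The real arrays gave 4 calls for genotype in old, 12 for genotype in young and 1 for the interaction.

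The alternatives were a further quantile normalisation, median centring of each array, omission of the 30% of probe sets with the lowest mean, eBayes without the trend, limma's array weights, a fit on only the arrays of the groups compared, the replicate number as a block, a minimum of 1.5-fold, windows of 5 and 20 Mb around Sh2b3 and omission of each replicate in turn. Other gene sets were also used for the age response. Added after the data were seen were a covariate for the mean level of 3 Y-linked genes (Eif2s3y, Kdm5d and Uty), a covariate for the SD of each array's values, and omission of the 5 arrays with Xist signal, defined as a log2 level above 6.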

Results

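Lnk, encoded by Sh2b3, is an adaptor protein that restrains cytokine signalling through JAK2, and mice without it carry more HSCs. The arrays asked how the transcriptome of HSCs changes between 2 and 20 months of age, and how it differs without Lnk at each age. RNA of sorted CD150+CD48- LSK cells from bone marrow was measured on 14 arrays, with 3 wild-type and 3 Lnk-null arrays from young mice and 4 wild-type and 4 Lnk-null arrays from old mice. The labels call the arrays of a group biological replicates, and p-values measure the spread between them. Array medians lay between 5.01 and 5.12 log2 units, and Pearson correlations between arrays lay between 0.984 and 0.995. The first principal component, with 26.9% of the variance, separated the ages. Old arrays lay between 3.87 and 19.5 on it, young Lnk-null arrays between -12.4 and -10.1 and young wild-type arrays between -23.2 and -18.6.

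Several further properties differed between arrays of a group. The labels state no sex. Xist, the RNA that coats the inactive X chromosome of females, was at 10.54 and 10.55 log2 units on young Lnk-null arrays 1 and 2, whose Y-linked genes averaged 3.06 and 3.00. Xist was also high on wild-type old arrays 1 and 2 (9.70 and 8.47) and wild-type young array 1 (9.89), with Y-linked means of 6.33, 7.06 and 6.59. These 3 arrays thus carried RNA of both kinds, and the labels do not say whether mice of both sexes were pooled. The other 9 arrays had Xist at or below 4.23 and Y-linked means of 6.99 to 7.31. All old Lnk-null arrays were among these 9, so genotype in old cells cannot be fully separated from sex. The SD of all values was 2.001, 2.042 and 2.008 on the young wild-type arrays and between 2.039 and 2.096 on all others, with the 2.039 on young Lnk-null array 3.

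The targeted gene was lower on every Lnk-null array than on every wild-type array of the same age. Sh2b3 stood at 7.59 ± 0.20 log2 units (SD, n = 4) in old wild-type HSCs and at 5.19 ± 0.19 (n = 4) in old Lnk-null HSCs. The difference was -2.40 ± 0.17 (SE), a 5.28-fold lower level (limma adjusted p = 2.9e-06), and the two-sided exact permutation p was 0.0286, the smallest possible with these group sizes. In young HSCs the means were 7.80 ± 0.18 and 5.34 ± 0.46 (n = 3 each). This 5.49-fold fall had a limma adjusted p of 8.6e-06, while the exact permutation p of 0.1 was the smallest the design allows. Which part of the transcript the probe set covers was not stated, so it was not settled whether the remaining 18.2% (young) and 18.9% (old) came from probes outside the deleted part. Sh2b3 itself did not pass the test for age in wild type (-0.21, adjusted p = 0.56) or in Lnk-null cells (-0.15, adjusted p = 0.90).

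**Figure D1:**
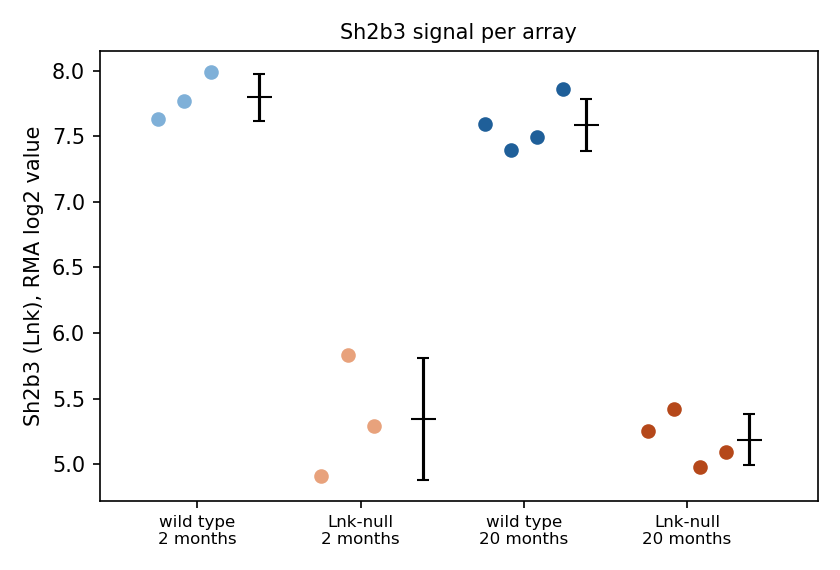
Log2 expression of Sh2b3 on each of the 14 arrays by group, with points for arrays, a bar for the group mean and an error bar for the SD. The wild-type means are 7.80 (young) and 7.59 (old), and the Lnk-null means are 5.34 and 5.19.

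Single genes rose and fell strongly with age in wild-type HSCs. Mt2, which encodes a metal-binding metallothionein, rose from 4.25 ± 0.87 (n = 3) to 9.26 ± 0.06 (n = 4), and Mt1 rose 5.49-fold. Selp, which encodes the platelet and endothelial adhesion molecule P-selectin, rose by 3.32 ± 0.23 log2 units (SE), and Plscr2, for a phospholipid scramblase, rose 11.2-fold (3.49 ± 0.16). Clca3a1 rose 6.80-fold, Bmpr1a, which encodes a BMP receptor, rose from 3.57 to 6.22 log2 units, and the NK-receptor gene Klrb1c from 3.73 to 6.24. No fold is given for genes whose lower group lay near the low end of the values. The MHC class II genes H2-Aa and H2-Eb1 rose 4.43-fold and 4.41-fold. The largest rises also took in Zg16 (2.50), Aspa (2.25) and Sbspon (2.21 log2 units). The largest fall was that of Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, at 3.76-fold (-1.91 ± 0.18). Flt3, a cytokine receptor gene of lymphoid-primed progenitors, fell 3.15-fold (-1.66 ± 0.14, adjusted p = 4.1e-06), and the cytokine signalling inhibitor gene Socs2 fell 3.30-fold (adjusted p = 0.031). Rassf4 (-1.48), Nrk (-1.44), Ebi3 (-1.44), Rgs7bp (-1.42), Plxdc2 (-1.41), Gria3 (-1.33), Igf1 (-1.23), Il12rb2 (-1.21) and Mgst1 (-1.17 log2 units) also fell. Of the genes followed throughout, Vwf rose by 1.34 and Slamf1, for the sort marker CD150, by 0.73. Jak2 (0.34), Cish (-0.49), Cdkn1a (0.54), Cdkn1c (0.14) and Procr (0.71) did not pass.

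In all, limma called 668 of 20239 genes between old and young wild-type HSCs, 454 higher and 214 lower with age, and 133 of them differed at least 2-fold. The old and young arrays did not overlap for 652 of the 668. Among all genes 15.3% did not overlap, against 5.71% by chance.

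The list of genes higher in aged HSCs in earlier studies rose with age in wild type. Of its 42 measured members, 34 rose and none fell, and 38 rose when adjusted over the list alone. Its median was 1.36 log2 units (camera adjusted p = 2.4e-65, and adjusted p = 0.00035 with an estimated correlation), with Aldh1a1, a retinaldehyde dehydrogenase gene, up by 1.88 ± 0.07 and Cavin2 by 1.71. The list was recalled from earlier work, part of which may have used these arrays, and is not independent evidence. Of 24 genes reported lower in aged HSCs, 6 fell, among them Flt3, Rassf4, Satb1 (-1.01), a chromatin organiser of lymphoid cells, and Cd34 (-0.84). There were 7 falls adjusted over the list alone. This list's median was -0.21 (adjusted p = 2.9e-07, and adjusted p = 0.067 with an estimated correlation). Megakaryocyte and platelet genes were higher, with 10 of 26 up (11 adjusted over the list alone), none down and a median of 0.48. The members included Clu (1.99), Cavin2, Selp and Vwf, which encodes von Willebrand factor (adjusted p = 6.1e-14, and adjusted p = 0.047 with an estimated correlation). Among 27 HSC identity genes, 5 rose, including Hoxb5 (0.95), Slamf1 and Esam (0.66), and Cd34 fell. There were 7 rises and 2 falls adjusted over the list alone, and the median was 0.11 (adjusted p = 1.1e-05, and adjusted p = 0.085 with an estimated correlation).

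Signalling genes of several groups were also higher in old wild-type HSCs. Of 29 immediate-early genes, which respond within minutes to stimulation, 6 rose, among them Zfp36 (1.13), Ier2 (0.98), Klf6 (0.88) and Rgs1 (0.55). A total of 13 rose adjusted over the list alone, and the median was 0.55 (adjusted p = 9.5e-10, and adjusted p = 0.11 with an estimated correlation). Of 36 interferon response genes, 5 rose, including the immunity-related GTPase genes Ifi47 (1.08), Igtp (1.03) and Iigp1 (0.95), and Bst2 (0.53). Adjusted over the list alone 10 rose and 1 fell, and the median was 0.23 (adjusted p = 1.4e-06, and adjusted p = 0.25 with an estimated correlation). With the SD of the arrays as a covariate that median fell to 0.01, and the test no longer passed and pointed down relative to the other genes. NF-kappaB and inflammation genes had 4 of 28 up, Bcl3 (0.92), Tnfaip2 (0.79), the inhibitor gene Nfkbia (0.48) and Sod2 (0.36). Adjusted over the list alone 4 rose and 1 fell (median 0.16, adjusted p = 4e-05, and adjusted p = 0.045 with an estimated correlation). TGF-beta and BMP genes had 4 of 29 up, Bmpr1a, Neo1 (1.29), Id2 (1.23) and Tgfb3 (0.54), and 8 up and 2 down adjusted over the list alone (median 0.08, adjusted p = 0.00092, and adjusted p = 0.045 with an estimated correlation). Of 32 JAK2 and STAT5 signalling genes and targets, 6 rose, including Osmr (1.91), which encodes a receptor subunit for oncostatin M, Bcl6 (2.39-fold), Ccnd1 (0.99) and Stat3 (0.56), and Socs2 fell. The counts adjusted over the list alone were 9 up and 1 down (median 0.06, adjusted p = 0.00086, and adjusted p = 0.045 with an estimated correlation).

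Cell cycle genes were lower as a group. Mitosis genes had a median of -0.43, with Ect2 (-0.91) and Kif23 (-0.77), which act in cytokinesis, the 2 of 29 that fell, and 2 adjusted over the list alone (adjusted p = 3.6e-06, and adjusted p = 0.39 with an estimated correlation). No DNA replication gene of 32 was called, nor any adjusted over the list alone (median -0.22, adjusted p = 0.0022, and adjusted p = 0.49 with an estimated correlation). DNA methylation and Polycomb genes had 2 of 29 down, Satb1 and Tet1 (-0.40), and adjusted over the list alone 4 down and 1 up (median -0.14, adjusted p = 0.043, and adjusted p = 0.088 with an estimated correlation). None of 24 p53 targets and CDK inhibitors was called over all genes and 7 rose adjusted over the list alone, with Plk2 at 1.85 (adjusted p = 0.065 over all genes). The list median was 0.09 (adjusted p = 0.027, and adjusted p = 0.085 with an estimated correlation).

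Metabolic and protein-folding lists shifted by small amounts. Redox and FoxO genes had 4 of 28 up, Mt1, Mt2, Sod2 and Gclm (0.46), a glutathione synthesis gene, and Hmox1 down, with the same counts adjusted over the list alone (median 0.14, adjusted p = 0.0008, and adjusted p = 0.088 with an estimated correlation). Dnajb9 (0.57) was the 1 heat shock and protein folding gene of 27 that rose, and 5 rose adjusted over the list alone (median 0.13, adjusted p = 0.0008, and adjusted p = 0.15 with an estimated correlation). Glycolysis and hypoxia genes had 2 of 25 up, Ndrg1 (0.73) and Pfkp (0.51), and 3 adjusted over the list alone (median 0.08, adjusted p = 0.0053, and adjusted p = 0.19 with an estimated correlation). Oxidative phosphorylation genes, 38 in number, had a median of 0.09 (adjusted p = 0.00086, and adjusted p = 0.35 with an estimated correlation) and ribosomal protein genes, 26 in number, a median of 0.04 (adjusted p = 0.033, and adjusted p = 0.41 with an estimated correlation). No member of either was called, over all genes or adjusted over the list alone.

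Markers of other cell types moved in both directions in old wild-type HSCs. Macrophage markers were lower, with 4 of 19 down, Hmox1, C1qb (-0.73), the cathepsin gene Ctss (-0.71) and the iron exporter gene Slc40a1 (-0.60), and 6 adjusted over the list alone (median -0.18, adjusted p = 1.1e-05, and adjusted p = 0.021 with an estimated correlation). Of 17 plasma and mature B cell markers, the 4 that rose were the MHC class II genes H2-Aa, H2-Eb1, Cd74 (1.83) and H2-Ab1 (1.60), and 1 fell, with the same counts adjusted over the list alone. That list's test pointed up and its mean was 0.39, while its median was -0.04 (adjusted p = 0.033, and adjusted p = 0.088 with an estimated correlation). Lists that did not pass were lymphoid priming and B lineage (adjusted p = 0.11, with Flt3 and Satb1 down), myeloid (0.16), erythroid (0.31), DNA repair (0.097), adhesion and niche (0.097, with 6 up and 3 down), T and NK cells (0.12), endothelial and stromal (0.33), mast cells and basophils (0.97) and sex-linked genes (0.97). Adjusted over the list alone, adhesion and niche genes had 9 up and 6 down, and T and NK markers 2 up and 4 down. With the SD of the arrays as a covariate, added after the data were seen, 49 genes were called, 48 of them among the 668. Of 64 calls of named genes, 16 were kept. The young wild-type arrays had low SDs, so the covariate overlaps with that group and also widens standard errors. For Sh2b3 in young cells the genotype difference went from -2.457 to -2.393 and its SE from 0.191 to 0.298. A call lost with this covariate thus does not by itself show that spread caused the difference. That covariate also ended the calls of the JAK2 and STAT5, redox, heat shock, oxidative phosphorylation, ribosomal protein, p53, and plasma and mature B cell lists. A further quantile normalisation ended those of the glycolysis, heat shock, oxidative phosphorylation, p53 and ribosomal protein lists. The DNA methylation list lost its call in 8 of 15 alternatives, with the Y-linked level as a covariate, without the 5 arrays with Xist signal, with an estimated correlation and in 5 of the 7 fits without 1 replicate. In fits without 1 replicate, calls were also lost for DNA replication, p53, plasma and mature B cell, oxidative phosphorylation and ribosomal protein genes. Without the 5 arrays with Xist signal, 231 were called, 197 of them shared, and a fit on the wild-type arrays alone called 380.

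**Figure D2:**
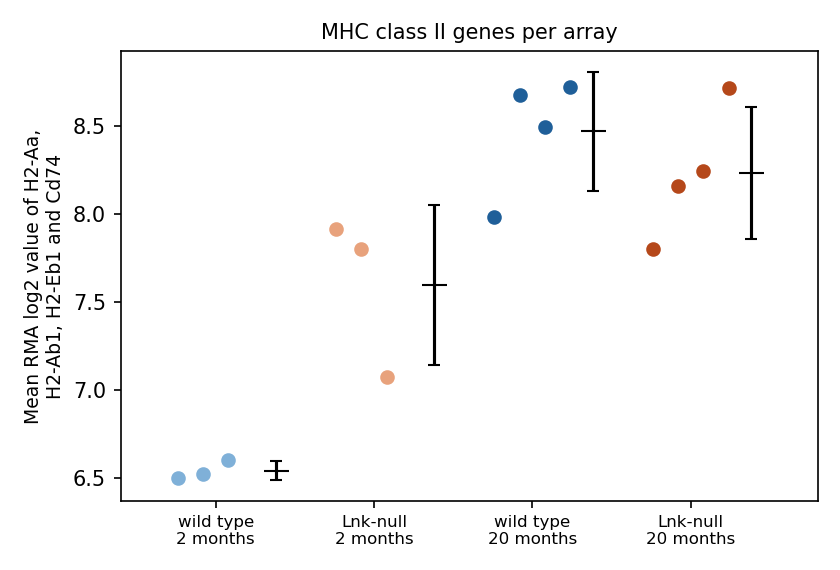
Mean log2 level of the MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 on each array by group, with points for arrays, a bar for the group mean and an error bar for the SD. Young wild-type arrays lie between 6.50 and 6.60, young Lnk-null arrays between 7.07 and 7.91, and old arrays between 7.80 and 8.72.

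**Figure D3:**
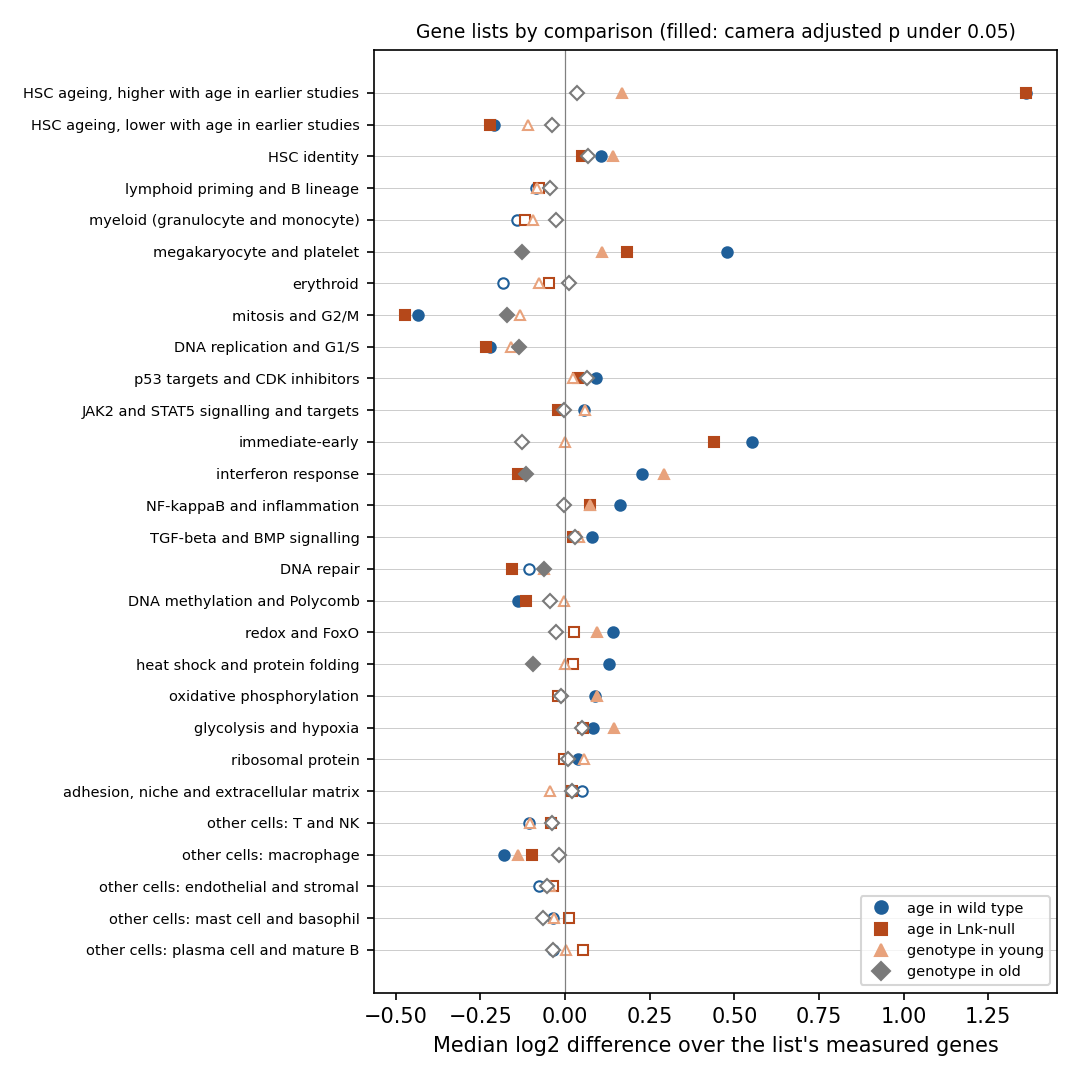
Median log2 difference of each gene list in each comparison, with the sex-linked list left out, and filled markers for lists with a camera adjusted p under 0.05 at the preset correlation. The list of genes higher in aged HSCs has a median of 1.36 for age in both genotypes, and the interferon list lies at 0.23 for age in wild type and -0.14 for age in Lnk-null. Not drawn are the interferon medians with a covariate. They were 0.12 for age in Lnk-null with the Y-linked level and 0.01 for age in wild type with the array SD.

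Ageing without Lnk raised many of the genes that rose in wild type. In Lnk-null HSCs Mt2 rose 14.3-fold (3.83 ± 0.43 log2 units, SE), Plscr2 5.92-fold (2.57 ± 0.16), Selp 5.50-fold (2.46 ± 0.23) and Clca3a1 5.27-fold (2.40 ± 0.11), with n = 4 old and n = 3 young arrays. Gpr183, which encodes an oxysterol receptor that guides immune cells, rose 6.55-fold, and Vldlr, a lipoprotein receptor gene, 5.64-fold, and the oncostatin M receptor gene Osmr rose from 3.57 to 6.07 log2 units. Trac, the constant region of the T cell receptor alpha chain, rose from 3.29 ± 0.40, near the low end of the values, to 6.32 ± 0.61, while the list of T and NK markers did not pass (median -0.04, adjusted p = 0.86). Klrb1c (2.40), Cd53 (2.32), Zg16 (2.21), the tight junction gene Cldn5 (2.19) and Bmpr1a (2.18) rose as well. The falls were smaller. Il12rb2 and Ebi3 each fell by 1.36, Mc5r by 1.35, Ldb2, for a cofactor of LIM-domain proteins, by 1.30 and Anxa6 by 1.23 log2 units. Rassf4 (-1.17), Phldb2 (-1.16), Rnase6 (-1.14), Tpm2 (-1.14), Rgs7bp (-1.12), Nrk (-1.10) and Mgst1 (-1.09) fell too. Vwf rose by 0.88, Slamf1 by 0.58 and Flt3 fell by 0.73 (adjusted p = 0.012). Jak2 (-0.08), Cish (-0.75), Cdkn1a (0.61), Cdkn1c (0.01), Procr (0.72) and Hmox1 (-0.65, adjusted p = 0.12) did not pass.

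The test called 272 genes, 198 higher and 74 lower with age, of which 107 differed at least 2-fold. The arrays did not overlap for 270 of them, and among all genes 9.93% did not overlap against 5.71% by chance. Of the 42 genes reported higher in aged HSCs, 31 rose in Lnk-null cells and 38 did adjusted over the list alone (median 1.36, adjusted p = 9.4e-89, and adjusted p = 8.7e-05 with an estimated correlation), including Enpp5 (1.36) and Cavin2 (1.41). Of the 24 reported lower, 3 fell, Flt3, Satb1 (-0.92) and Rassf4, and 6 adjusted over the list alone (median -0.22, adjusted p = 1.9e-08, and adjusted p = 0.072 with an estimated correlation). Megakaryocyte and platelet genes had 5 up, among them Clu (1.67), Itgb3 (1.41) and Cavin2, and adjusted over the list alone 7 up and 1 down (median 0.18, adjusted p = 6.4e-09, and adjusted p = 0.12 with an estimated correlation). HSC identity genes had Slamf1 and Trim47 (1.09) up, and adjusted over the list alone 4 up and 1 down (median 0.05, adjusted p = 0.0093, and adjusted p = 0.25 with an estimated correlation). DNA methylation and Polycomb genes were lower, with Satb1 called and 5 down adjusted over the list alone, and Dnmt3b at -0.38 (median -0.11, adjusted p = 0.00023, and adjusted p = 0.015 with an estimated correlation). Neither this list (adjusted p up to 0.13) nor HSC identity (up to 0.413) passed with the Y-linked level as a covariate or without the 5 arrays with Xist signal.

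Immediate-early genes had no member called over all genes and 12 up adjusted over the list alone, with Fos at 1.84 and Egr1 at 1.42 (median 0.44, adjusted p = 7.7e-10, and adjusted p = 0.13 with an estimated correlation). Of the JAK2 and STAT5 list, 5 rose, including Osmr, Bcl6 (1.33), Socs3 (1.18), a feedback inhibitor of cytokine receptors, and Stat3 (0.41), and adjusted over the list alone 8 rose and 2 fell. Its test pointed up with a mean of 0.18 and a median of -0.02 (adjusted p = 0.038, and adjusted p = 0.13 with an estimated correlation). NF-kappaB genes had 3 up, Il1r1 (1.31), Bcl3 (1.23) and Nfkbia (0.55), and adjusted over the list alone 5 up and 3 down (median 0.07, adjusted p = 0.016, and adjusted p = 0.16 with an estimated correlation). TGF-beta and BMP genes had 4 up, among them Tgfbi (1.64), Id2 (1.22) and Neo1 (1.19), and adjusted over the list alone 6 up and 1 down (median 0.02, adjusted p = 0.0061, and adjusted p = 0.072 with an estimated correlation), and the call was lost without the 5 arrays with Xist signal. The interferon list was lower, with Ifi27l2a (-1.06) called and 5 down adjusted over the list alone (median -0.14, adjusted p = 0.0011, and adjusted p = 0.44 with an estimated correlation). That list turned upward, to a median of 0.12, with the Y-linked level as a covariate, and passed in that direction (camera adjusted p = 0.031). Its median was 0.14 without the 5 arrays with Xist signal, a fit that left only array 3 of the young Lnk-null group. The direction of the list for age in Lnk-null thus depended on how sex was handled.

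Mitosis genes had a median of -0.47 with none called and 2 down adjusted over the list alone (adjusted p = 1.2e-11, and adjusted p = 0.25 with an estimated correlation). DNA replication genes (median -0.23, adjusted p = 1.2e-05, and adjusted p = 0.41 with an estimated correlation) and DNA repair genes (median -0.16, adjusted p = 0.0033, and adjusted p = 0.44 with an estimated correlation) had no member called either way. Under the same settings none of the 3 lists passed, with mitosis at an adjusted p of up to 0.331, and the DNA replication and DNA repair tests pointed up relative to the other genes. Neither way of adjusting called a p53 target or CDK inhibitor (median 0.04, adjusted p = 0.016, and adjusted p = 0.072 with an estimated correlation). Among macrophage markers Ctss fell by 0.85, and 2 fell adjusted over the list alone (median -0.10, adjusted p = 0.016, and adjusted p = 0.12 with an estimated correlation). The sex-linked list was higher in old Lnk-null cells, with Uty up by 2.67 and adjusted over the list alone 3 up and 1 down (median 2.38, adjusted p = 0.0018, and adjusted p = 0.072 with an estimated correlation). All 4 old Lnk-null arrays and 1 of the 3 young ones had Y-linked RNA without Xist. With the Y-linked level as a covariate 74 genes were called, 59 of them among the 272, and 71 were called without the 5 arrays with Xist signal, 53 of them shared. Of 46 calls of named genes, 17 were kept with that covariate and 18 without those arrays. In fits without 1 replicate, the calls of the JAK2 and STAT5, NF-kappaB, interferon, DNA repair, p53 and macrophage lists were lost at least once.

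The age effects in wild type and Lnk-null HSCs, which share no arrays, ran largely the same way. Across genes their Pearson correlation was 0.558 and their Spearman correlation 0.301, and genes are not independent replicates. There were 152 genes called higher with age in both genotypes, against 4.44 from independent lists, 34 called lower in both, against 0.782, and none called in opposite directions. Of the genes called in wild type 89.5% had the same sign in Lnk-null, and of those called in Lnk-null 96.7% had the same sign in wild type. A further 482 genes were called in wild type and not in Lnk-null, and none of these passed the interaction test, in which 1452 genes had an unadjusted p under 0.05.

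**Figure D4:**
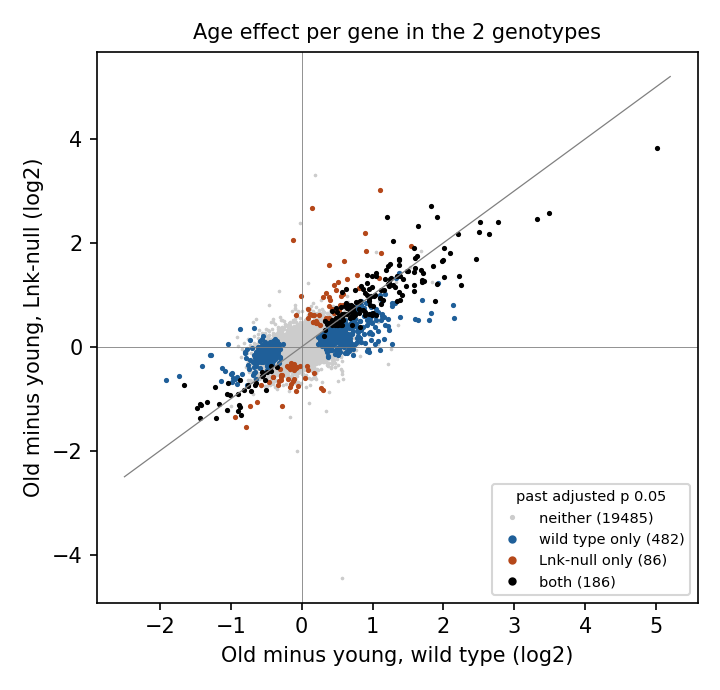
Age effect (old minus young, log2) of each tested gene in wild type on the horizontal axis and in Lnk-null on the vertical axis, with colour for genes called in either or both. The 152 genes called higher and 34 called lower in both genotypes lie in the upper right and lower left.

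Aldh1a1 was the only gene whose age effect differed between the genotypes by limma's interaction test. It rose with age by 1.88 ± 0.07 log2 units in wild type and by 0.88 ± 0.07 in Lnk-null, an interaction of -1.005 ± 0.10 (adjusted p = 0.00061). It stood at 8.14 ± 0.06 in young wild-type and 9.15 ± 0.16 in young Lnk-null cells, and at 10.02 in both old groups. The interaction did not pass with the array SD as a covariate, nor without the 5 arrays with Xist signal, and its adjusted p ranged up to 0.284. Flt3 (0.93, adjusted p = 0.37), Selp (-0.87, adjusted p = 0.64), Vwf (-0.46) and Jak2 (-0.42) did not pass. Camera called 9 lists for the interaction at the preset correlation, and none of them passed with an estimated one or with the array SD as a covariate (interferon adjusted p = 0.189). The interferon list was the furthest shifted of the 7 lower ones, with Iigp1 at -1.05 and Ifi47 at -0.98, and 5 members down adjusted over the list alone (median -0.38, adjusted p = 6.3e-15, and adjusted p = 0.33 with an estimated correlation). The others were HSC ageing higher (-0.11, adjusted p = 0.0019), HSC identity (-0.05, 0.042), megakaryocyte and platelet (-0.24, 0.00021), heat shock (-0.08, 0.037) and oxidative phosphorylation (-0.12, 0.00021), each with an adjusted p of 0.48 with an estimated correlation. Redox genes were lower too (-0.09, adjusted p = 0.014, and adjusted p = 0.47 with an estimated correlation). Macrophage markers (0.14, adjusted p = 0.0081) and sex-linked genes (2.40, adjusted p = 0.014) were higher, each with an adjusted p of 0.32 with an estimated correlation. Adjusted over the list alone, the counts were 2 down for HSC ageing higher, 2 for HSC identity, 1 for megakaryocyte genes, 1 up and 1 down for redox genes, 1 up for macrophage markers and 4 up for sex-linked genes.

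Over the 929 genes called for the mean age effect, 616 higher and 313 lower with age, the mean signed age effect was 0.644 log2 units in wild type and 0.546 in Lnk-null. The difference of -0.0979 gave a two-sided exact permutation p of 0.147 over 1400 arrangements, and a ratio of 0.848. Over all genes tested the difference was -0.0484 (exact permutation p = 0.0886) and over the 2 HSC ageing lists -0.136 (exact permutation p = 0.259), and omission of 1 array moved it between -0.156 and -0.0359. The effect was smaller in Lnk-null for 602 of the 929 genes (64.8%). On the age score built from these genes, young wild-type arrays lay at 0 ± 0.0165 (SD, n = 3) by construction and young Lnk-null arrays at 0.126 ± 0.0123 (n = 3), with every Lnk-null array (0.119 to 0.140) above every wild-type one (-0.0187 to 0.0125). That difference was 19.6% of the wild-type age response, and its two-sided exact permutation p of 0.1 was the smallest 3 arrays against 3 can give. Old wild-type arrays averaged 0.644 ± 0.0534 (n = 4) and old Lnk-null arrays 0.672 ± 0.0544 (n = 4). Their difference of 0.0281 lay inside the spread of the arrays (two-sided exact permutation p = 0.514, smallest possible 0.0286).

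**Figure D5:**
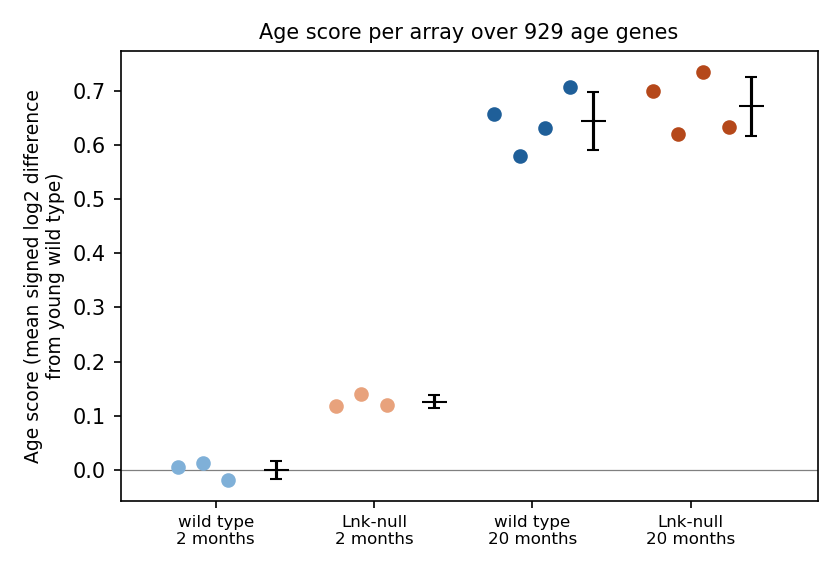
Age score of each array, the mean signed log2 difference from the young wild-type mean over 929 age genes, with points for arrays, a bar for the group mean and an error bar for the SD. The young Lnk-null mean is 0.126, and the old groups average 0.644 and 0.672.

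Few genes were called between old Lnk-null and old wild-type HSCs. Besides Sh2b3, limma called 3 genes. Itpr2, which encodes an inositol trisphosphate receptor that releases calcium from internal stores, was 1.84-fold higher in Lnk-null cells (0.88 ± 0.09 log2 units, SE, adjusted p = 0.00045, n = 4 each). P2ry10, a lysophospholipid receptor gene, was higher (0.76 ± 0.12, adjusted p = 0.047) near the low end of the range, at 3.50 against 2.74. Pcdh7, a protocadherin gene, was 2.07-fold lower (-1.05 ± 0.16, adjusted p = 0.038). Without the 5 arrays with Xist signal Itpr2 no longer passed (adjusted p = 0.0945 at its highest over all settings). P2ry10 and Pcdh7 reached adjusted p-values of up to 0.633 and 0.146 under other settings, including most fits without 1 of the replicates. At an unadjusted p under 0.05 there were 1017 genes, close to the share of the 20239 genes tested that chance alone gives at that threshold. Flt3 (0.38), Slamf1 (0.31), Procr (0.19), Cdkn1c (0.14), Selp (0.13), Vwf (0.05), Cish (-0.07), Jak2 (-0.08) and Cdkn1a (-0.19) did not pass.

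Camera called 6 lists lower in old Lnk-null HSCs, with no member called in any. They were interferon response (median -0.12, adjusted p = 0.00036, with Usp18 at -0.41), heat shock and protein folding (-0.09, 0.00036, with Hspa1a at -1.82), mitosis (-0.17, 0.00096, with Bub1 at -0.39), DNA replication (-0.13, 0.004), megakaryocyte and platelet (-0.13, 0.014) and DNA repair (-0.06, 0.019). Each had an adjusted p of 0.89 with an estimated correlation, and adjusted over the list alone only Hspa1a, for an inducible heat shock protein, was called. Without the 5 arrays with Xist signal only the interferon list of these 6 still passed. None of 242 genes within 10 Mb of Sh2b3 was called in old or young cells, and as a group they gave an unadjusted camera p of 0.66 in old (median -0.00398) and 0.87 in young cells (median -0.03).

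Few genes were called between young Lnk-null and young wild-type HSCs, with 3 arrays against 3. Aldh1a1, the retinaldehyde dehydrogenase gene, was 2.01-fold higher in Lnk-null cells (1.01 ± 0.08 log2 units, SE, adjusted p = 8.6e-06, n = 3 each). Plscr2 was 2.29-fold higher (1.20 ± 0.17, adjusted p = 0.014) and Slco2a1, a prostaglandin transporter gene, 2.21-fold (1.14 ± 0.17, adjusted p = 0.019). The retinaldehyde reductase gene Dhrs3 (1.06), Cyyr1 (1.03), the galactosyltransferase gene B3galt1 (0.90), Trim12c (0.77), Itpr2 (0.68) and Itih5 (0.54) were also higher. Hmox1 was 3.03-fold lower, at 5.47 ± 0.37 against 7.07 ± 0.29 (-1.60 ± 0.19, adjusted p = 0.0025). With Sh2b3, and with a microRNA gene, Mir665 (-0.74), named after its value was seen, these made 12 calls, 9 higher and 3 lower. The comparison subtracts the same young wild-type arrays as that of age in wild type, so chance values of those arrays enter both, and the overlap of the 2 comparisons was not tested. At an unadjusted p under 0.05 there were 2278 genes, against 1017 between the old groups. That is more than the share of the genes tested that chance alone gives at that threshold. Among all genes 15.9% did not overlap between the groups, against 10% by chance. The small number of calls therefore does not show that the young groups were alike. Selp (0.99, adjusted p = 0.19), Vwf (0.51), Slamf1 (0.46), Jak2 (0.34), Cdkn1c (0.26), Cish (0.19), Procr (0.18), Cdkn1a (-0.27) and Flt3 (-0.54) did not pass.

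Camera called 10 lists between the young groups, 8 higher and 2 lower in Lnk-null, and none with an estimated correlation. Only the glycolysis list and the list of genes higher in aged HSCs kept their call under the other settings run on lists, which did not include array weights, a fit without the trend or a fit on the young arrays alone. Interferon response genes had no member called over all genes and 4 up adjusted over the list alone, with Iigp1 at 0.79 and Ifi47 at 0.62 (median 0.29, adjusted p = 3.8e-10, and adjusted p = 0.26 with an estimated correlation). With the array SD as a covariate that median was 0.04 and the test, which no longer passed, pointed down relative to the other genes. Of the genes reported higher in aged HSCs, Aldh1a1 and Plscr2 were higher, with 10 up adjusted over the list alone (median 0.17, adjusted p = 4.4e-05, and adjusted p = 0.26 with an estimated correlation). HSC identity genes had a median of 0.14 with none called either way (adjusted p = 8.1e-05, and adjusted p = 0.26 with an estimated correlation). Glycolysis genes had a median of 0.15 and 3 up adjusted over the list alone, with Aldoc at 0.61 (adjusted p = 0.00049, and adjusted p = 0.26 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.10 (adjusted p = 0.0002, and adjusted p = 0.41 with an estimated correlation), and megakaryocyte genes a median of 0.11 with 2 up adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.50 with an estimated correlation). Redox genes were higher at a median of 0.09, with Hmox1 lower and, adjusted over the list alone, 2 up and 1 down (adjusted p = 0.0045, and adjusted p = 0.26 with an estimated correlation). NF-kappaB genes had a median of 0.07 and 2 up adjusted over the list alone (adjusted p = 0.047, and adjusted p = 0.28 with an estimated correlation).

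Macrophage markers were lower in young Lnk-null cells, with Hmox1 called and, adjusted over the list alone, 3 down and 1 up (median -0.14, adjusted p = 0.007, and adjusted p = 0.23 with an estimated correlation). Sex-linked genes were lower as well, with Eif2s3y at -3.01 and 4 down adjusted over the list alone (median -2.03, adjusted p = 0.0045, and adjusted p = 0.23 with an estimated correlation). This list follows young Lnk-null arrays 1 and 2, on which Xist was high and the Y-linked genes were low. With the Y-linked level as a covariate 13 genes were called, 4 of them among the 12, while 5 were called without the 5 arrays with Xist signal and 2, shared with the 12, with the array SD as a covariate. The count also rose, to 21 without dim probe sets, 25 with array weights, and 37 and 36 without wild-type array 2 and Lnk-null array 3. Aldh1a1 passed under every setting tried, and Hmox1 under all but the array SD covariate (adjusted p = 0.231).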

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

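The tests of the age score and of the MHC class II genes were chosen only after the results were seen, and the other tests of this part were planned.

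Aldh1a1 was the gene whose age effect differed between the genotypes, with an interaction of -1.005 log2 units. The 9 lists that camera called for the interaction at the preset correlation also stood out, and none was called with an estimated correlation. Their medians were -0.11 for HSC ageing higher, -0.04537 for HSC identity, -0.2352 for megakaryocyte and platelet, -0.3786 for interferon response, -0.08524 for redox, -0.08433 for heat shock, -0.1205 for oxidative phosphorylation, 2.402 for sex-linked genes and 0.1413 for macrophage markers.

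Within the groups of 4, single arrays lay far from the other 3 for 7 named genes. Old Lnk-null array 2 had Rgs7bp at 3.464 (others 3.70 to 3.73) and Cldn5 at 5.646 (others 6.62 to 6.67). Old Lnk-null array 3 had Dnajb9 at 8.549 (others 7.84 to 7.94). Among old wild-type arrays, array 1 had H2-Eb1 at 7.648 (others 8.06 to 8.13), array 2 had Clu at 8.624 (others 8.93 to 8.98), array 3 had Slc40a1 at 3.268 (others 3.17 to 3.18) and array 4 had Tgfb3 at 4.688 (others 4.53 to 4.55). Chance gives such a value in about 1 in 20 groups, or 9.6 of the 192 tested, so 7 is no excess. The probe sets without a gene name here, 986 in number, also carried age signal, with 18 called for age in wild type (13 higher, 5 lower) and 7 for age in Lnk-null (6 higher, 1 lower).

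Other splits of the same arrays bear on how far the counts could arise without the labels. For age in wild type, 1 of the 35 splits, the real one, gave as many as 668 genes, and the highest other, which only moved old array 2 to the young arrays, gave 223, so chance is argued against. For age in Lnk-null 1 of 35 splits gave as many as 272 genes (highest other 6), and for the mean age effect 1 of 100 drawn gave as many as 929 (highest other 153), so chance is argued against there too. For genotype in old 2 of 35 splits gave at least the 4 genes found. The highest other, which grouped wild-type array 2 with Lnk-null arrays 1, 2 and 4, gave 10, and chance cannot be excluded. For the interaction 12 of 100 gave at least the 1 gene found (highest other 2), and chance cannot be excluded. For genotype in young the 10 splits allow no share under 0.1. The real split, the 1 that gave as many, called 12 genes and the highest other 1.

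The counts of called lists at the preset correlation were less specific to the labels. For age in wild type the real count of 20 was reached by 1 of 35 splits (highest other 18), and for age in Lnk-null the count of 16 by 1 of 35 (highest other 14). The real split ranked first in each, but other splits came close. These counts therefore do not show that any single list was called because of age. For genotype in old 20 of 35 splits gave at least the 6 lists found (highest other 12), and for the interaction 26 of 100 gave at least 9 (highest other 13), so chance cannot be excluded for either. For genotype in young the 10 splits allow no share under 0.1. The real value was 10 and the highest other 13, with 3 splits at least as high.

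Young Lnk-null arrays lay above young wild-type arrays on the age score, with a mean of 0.126 against 0 by construction. Whether a difference in sex is the whole cause cannot be decided. With the Y-linked level in the model the difference was 0.123 (95% interval 0.0136 to 0.232). That fit mainly sets young Lnk-null arrays 1 and 2, with low Y-linked RNA, against array 3 of the same group. Young Lnk-null array 3, which had Y-linked RNA and no Xist, scored 0.119, above every young wild-type array. Both values thus rest on the same array. The narrower spread of values on the young wild-type arrays stays open, since with the array SD in the model the difference was 0.111 (95% interval -0.014 to 0.235). Young Lnk-null array 3 had an SD of 2.039, within the range of the young wild-type arrays (2.001 to 2.042). Its score thus bears on spread as well as on sex, but it is a single array. Loss of Lnk itself may also account for it and cannot be decided, as the exact permutation p of 0.1 is the smallest that 3 arrays against 3 can give.

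The MHC class II genes averaged 1.93 log2 units higher in old than in young wild-type HSCs, and 1.05 higher in young Lnk-null than in young wild-type HSCs, and both differences subtract the same 3 arrays. Mature B cells in the sort, which the lineage gate should remove, are argued against for the age difference. The other 13 plasma and mature B cell genes had a median age change of -0.0668 (SE 0.0845 over the genes, not over arrays). That lay below 0.482, a limit set after the results were seen as a fixed share of the MHC class II rise. Cd79a (2.56 to 3.42), Ms4a1 (2.49 to 3.12) and Jchain (2.48 to 3.04) stayed low on every array. Macrophages are argued against likewise, with a median of -0.182 (SE 0.131 over the genes) over 19 markers, while other cells with MHC class II were not tested. For the young difference sex may contribute: with the Y-linked level in the model it was 0.686 (95% interval -0.0818 to 1.45). The young Lnk-null arrays with Xist stood at 7.91 and 7.80, and array 3 stood at 7.07, still above the young wild-type arrays (6.50 to 6.60). Array 3 also had a lower SD of values (2.039) than arrays 1 and 2 (2.088 and 2.096), so sex and spread cannot be told apart there. Wild-type arrays with Xist were not all higher. Young array 1 (6.50) and old array 1 (7.99) were the lowest of their groups, while old array 2 stood at 8.68. With the array SD in the model the young difference was 0.438, and the age rises in wild type were 1.034 (H2-Ab1) to 1.482 (H2-Eb1) with none called, so spread stays open for both differences, beside age in wild type and genotype and sex in the young.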

How the results depend on the processing

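The settings with a covariate for the Y-linked level or the array SD, and without the 5 arrays with Xist signal, were chosen only after the data were seen, and the others were planned. With the inter-gene correlation estimated, 6 lists were called for age in wild type, 2 for age in Lnk-null and 0 each for genotype in old, genotype in young and the interaction, where 1452 genes had an unadjusted p under 0.05 and 1 passed adjustment. The planned setting with every probe set of exactly 1 symbol gave identical values, as no gene had a second probe set. For genotype in young, the count of 12 genes became 6 after a further quantile normalisation, 21 without dim probe sets, 25 with array weights and 5 on the young arrays alone. For genotype in old, 2 genes were called without the variance trend. For age in Lnk-null, array weights called 428 genes. For age in wild type, 380 were called on the wild-type arrays alone and 345 at a minimum of 1.5-fold, which left 321 for the mean age effect. The cause was not tested for these.

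With the Y-linked covariate 74 genes were called for age in Lnk-null, 3 for the interaction and 616 for the mean age effect, with 6 lists for genotype in young and 4 for the interaction. For age in Lnk-null the tests of DNA replication (median -0.05517), interferon response (0.1229) and DNA repair (0.03756) turned upward relative to other genes. Of these only the interferon test passed in that direction (camera adjusted p = 0.031). With the array SD covariate 49 genes were called for age in wild type, 2 for genotype in young, 0 for the interaction and 372 for the mean age effect, with 13 lists for age in wild type and 3 for the interaction. The interferon (0.01009), oxidative phosphorylation (-0.04267) and ribosomal protein (-0.06225) tests reversed for age in wild type. So did interferon (0.03569) and oxidative phosphorylation (-0.02327) for genotype in young, and heat shock (-0.02109) and oxidative phosphorylation (0.002762) for the interaction. Without the 5 arrays with Xist signal, fewer arrays called 231 genes for age in wild type, 71 for age in Lnk-null, 5 for genotype in young, 0 for the interaction and 416 for the mean age effect, and 1 list for genotype in old. DNA replication (-0.05447), interferon (0.1399) and DNA repair (0.03589) reversed for age in Lnk-null, as did sex-linked genes for genotype in young (0.147), and heat shock (-0.02712) and sex-linked genes (-0.1704) for the interaction. The cause was not tested.

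Leaving out 1 replicate gave 382 to 697 genes for age in wild type (411 without old array 3, 443 without old array 4, 382 without young array 1, 440 without young array 3) and 152 to 249 for age in Lnk-null (152 and 167 without young arrays 1 and 2). It gave 2 to 8 for genotype in old (8 without wild-type array 1, 2 without wild-type array 3 or Lnk-null array 2 or 4) and 4 to 37 for genotype in young (7 and 37 without wild-type arrays 1 and 2, and 4, 5 and 36 without Lnk-null arrays 1, 2 and 3). It gave 1 to 6 for the interaction (6 without young Lnk-null array 3) and 713 to 1121 for the mean age effect. Lists ranged from 17 to 20, 12 to 17, 2 to 10 (2 without wild-type array 2 or Lnk-null array 3, 10 without Lnk-null array 2), 8 to 12, and 5 to 11 (5 without young wild-type array 3) in the same order. The difference in age response ranged from -0.1564 to -0.03594, the correlation of age effects from 0.4647 to 0.5698, and Sh2b3 from -2.48 to -2.311 in old and from -2.701 to -2.239 in young cells.

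Of 124 called results of named genes none changed sign in any setting. The call was kept for 123 with median centring, 111 with a further quantile normalisation, 119 without the trend, 118 with array weights, 103 of 123 on the compared arrays alone, 85 with the Y-linked covariate, 64 with the array SD covariate and 63 without the arrays with Xist signal. The replicate numbers share only a number: 2 of 19 same-numbered pairs had a correlation of deviations over 0.1 (range -0.03 to 0.27), and 4 of 14 arrays correlated best with their own number. With the replicate number as a block, 554 genes were called for age in wild type (485 shared), 255 for age in Lnk-null (220), 4 for genotype in old (3), 18 for genotype in young (10) and 1 for the interaction (1).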

Other observations

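The genes and groups of this part were chosen after their values were seen, and the test of the Y-linked covariate on cholesterol synthesis was planned before its result was seen. Meg3, the maternally expressed long noncoding RNA of the imprinted Dlk1-Dio3 region, stood at 5.59 ± 0.36 log2 units in young Lnk-null HSCs (SD, n = 3, range 5.25 to 5.97) and between 6.80 and 8.16 on the other 11 arrays. It rose with age in Lnk-null by 2.05 (limma adjusted p = 0.0028), and neither the difference from young wild type (-1.93, adjusted p = 0.056) nor the interaction (adjusted p = 0.35) passed. Dlk1, the paternally expressed neighbour, rose with age in Lnk-null by 1.58 (adjusted p = 0.015), and Mir665, a microRNA of the same region, was lower in young Lnk-null cells by the report's test. Thy1, a surface glycoprotein gene, fell with age in wild type by 0.67 (adjusted p = 0.0088) and had a value of 0.37 in Lnk-null (adjusted p = 0.30). S100a6, a calcium-binding protein gene, rose with age by 1.32 in wild type and 1.14 in Lnk-null. S100a4 rose by 1.03 in Lnk-null (adjusted p = 0.00098) and did not pass in wild type (0.35, adjusted p = 0.22). Dlk1 did not pass in wild type either (0.39, adjusted p = 0.53). The limma interaction did not pass for Dlk1 (adjusted p = 0.64), Thy1 (0.28) or S100a4 (0.60), so no difference in age effect between the genotypes was shown for them.

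Some further genes were looked at one by one, without a test of them as a group. For age in wild type the class I genes H2-T23 (0.65, adjusted p = 0.0024) and H2-D1 (0.35, adjusted p = 0.0041) rose, while H2-K1 (0.24, adjusted p = 0.062) and Tap1 (0.34, adjusted p = 0.20) did not pass. The GTPase genes Irgm2 (0.90, adjusted p = 0.0032) and Gbp8 (0.67, adjusted p = 0.046) rose, while Gbp9 (0.29, adjusted p = 0.38), Gimap3 (-0.54), Gimap4 (-0.01) and Gimap6 (-0.10) did not pass. Uba7, for the enzyme that activates ISG15, rose by 0.82 (adjusted p = 6.2e-06). In Lnk-null cells Uba7 rose by 0.38 (adjusted p = 0.013) and Gbp9 fell by 0.83 (adjusted p = 0.022). The limma interaction of Gbp9 did not pass (adjusted p = 0.39). Gimap3 and Gimap4, GTPase genes of lymphocyte survival, had differences of 1.47 and 1.23 between Lnk-null and wild type in old cells and of 0.79 and 1.02 in young cells, none of which passed. The Trac signal of old Lnk-null arrays had no counterpart in Cd3e (0.00), Cd3d (-0.07), Cd3g (0.01), Cd2 (-0.08) or Cd8a (-0.07) for age in Lnk-null, none of which was called. Trac signal was not limited to Lnk-null cells, as it stood at 5.53 on old wild-type array 1. Neither its difference between the old groups (2.28, limma adjusted p = 0.17) nor its interaction (adjusted p = 0.62) passed.

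Genes of cholesterol synthesis, a group picked after its values were seen, had lower age effects in Lnk-null than in wild type. All 18 had a negative interaction, with a median of -0.470 and no single gene called (camera p of 3.7e-14 at the preset correlation and 0.0167 with an estimated one, both unadjusted). With age the median was 0.0505 in wild type, where 8 of 18 were below 0, and -0.394 in Lnk-null, where all 18 were below 0. In Lnk-null 2 were called, including Cyp51 (-0.80, adjusted p = 0.0096), a sterol demethylase gene, and none with the Y-linked level as a covariate. Lnk-null minus wild type was 0.274 in young cells, with 1 of 18 below 0, and -0.228 in old cells. With the Y-linked level in the model the median interaction was -0.744 (SE 0.107 over the genes, not over arrays). That fit mainly sets young Lnk-null arrays 1 and 2, with low Y-linked RNA, against the only young Lnk-null array without Xist signal. It therefore cannot decide whether sex is the whole cause. The pattern was found and tested on the same arrays and stays a hypothesis, its cause is open, and the spread of the arrays and the handling of the sorts were not tested for it.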
